A study of Homo sapiens with 6 samples.

How the data were processed

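Gene expression was measured on Illumina bead arrays in SKOV-3, an established human ovarian cancer cell line. Per the labels, cells were transfected with a scramble control siRNA (siCtrl) or with siRNA against HBO1 (siHBO1), and total RNA was collected 48 h later and labelled with biotin. The labels give 3 arrays per group, numbered 1 to 3 in each, and no slide, scan or culture batch. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The siRNA sequences are not given in the sources used here.

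The deposited intensity of each probe is the array's mean bead signal on a linear scale, per the file headers, and its lowest values lie well above 0 with array totals that differ, so neither background subtraction nor scaling between arrays is visible in it. The deposited detection p-value of each probe, per the file headers, is counted against the array's negative control beads, and it moves in 770 steps per array. The authors' processed value table is on a log2 scale, judged from its values: each of its columns has a rank correlation of 1 with that array's intensities, and all columns share one distribution with a median of 5.99, a lowest value of 5.72 and a highest of 14.29. GenomeStudio and lumi are named in the submitters' processing notes, with no version or role, and the exact background and normalization method behind that table is not given in the sources used here. No centring by gene is visible in the table, and it has no direction since it holds levels, not ratios.

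Each array holds 47314 probes. The probe table of the platform lists exactly 1 gene symbol for 30110 of them, several for 8 and none for 17196, and probes with several or none were kept under their probe identifiers as unnamed probes. Of the listed gene identifiers, 30071 were found in the reference gene table, and no symbol needed an update (0 changed). Mean signal per array was 713, 730 and 674 for siCtrl 1 to 3 and 643, 650 and 744 for siHBO1 1 to 3. Between 19946 and 20976 probes per array had a detection p under 0.05. For arrays, the number of arrays limits the precision.

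All values below come from limma 3.58.1 in R 4.3.3 with statmod 1.5.0. Intensities were background-corrected and quantile-normalized with neqc (normexp with parameters from the detection p-values, offset 16) and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 of the 6 arrays, whichever their group, were kept (20744 probes). For each gene the probe with the highest mean over all 6 arrays was used, which mattered for 3217 genes with more than 1 kept probe. This left 16692 rows, 11917 named genes and 4775 unnamed probes. Groups were compared with lmFit and eBayes with an intensity trend, two-sided, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The targeted gene also had an exact permutation test, for which 3 arrays against 3 allow no two-sided p below 0.1. The scripts were tested on 20 simulated data sets of 16692 rows with 200 changed rows for the comparison of siHBO1 with siCtrl. They recovered 12.1% of 1.5-fold, 58.1% of 2-fold and 95.8% of 3-fold changes at the same threshold, with a mean of 8.1 false calls, and made a mean of 0.35 calls where nothing was changed. The noise of these simulated arrays was drawn independently for each gene. Real arrays also differ by a component shared between genes, described in the closing sections, so these rates need not hold for them.

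Gene lists were fixed before the data were examined: partners of HBO1 in its complexes, other lysine acetyltransferases, replication licensing, DNA synthesis and E2F targets, mitosis, cell cycle inhibitors, replication-dependent histones, p53 targets, DNA repair, interferon response, NF-kB and cytokine genes, epithelial genes, mesenchymal genes, TGF-beta and YAP targets, stem cell genes, Wnt genes, HOX genes, steroid hormone receptors, ERBB and growth factor signalling, apoptosis regulators, stress and unfolded protein response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, ribosome biogenesis and MYC targets, oxidative phosphorylation, RNA interference machinery, reference genes, leukocyte markers, and fibroblast and endothelial markers. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, which compares a list's genes with all other genes, and again with the correlation estimated per list.

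The rule for named genes was also fixed before the data were examined. KAT7 and its complex partners are always named. The 12 largest changes per direction among genes past the threshold would be named, and where none passes, the 10 genes with the smallest p per direction are given as values. For each list the 3 largest changes past the threshold, or else the 2 members with the smallest p, are given. Unnamed probes are passed over, 3 among the lower and 2 among the higher genes, and provisional symbols would be too (0 were met).

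Alternatives tried were no background correction, normexp with offset 50, the authors' processed values, median scaling, cyclic loess, no filter on dim probes, detection p under 0.01 on all 6 arrays, the mean of a gene's probes, every probe on its own, no intensity trend, array weights, the replicate number as a block, each array left out in turn, an estimated list correlation, an adjusted p under 0.01, and a minimum change of 2-fold. An adjustment for the leading component of the residuals and a fit without the 2 arrays at its ends were added after the data had been seen. The median change of all genes stayed within 0.1 log2 of 0 under every normalization. Each of these puts the arrays on a common scale, which largely forces this, so a shift of all genes together could not have been seen. The leading component was inspected with genes chosen after their values were seen, named as such where they appear. Genomic positions were not used here, since the array's genome build is not given in the sources used here.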

Results

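Expression profiles were recorded from 6 arrays of SKOV-3 ovarian cancer cells, 3 transfected with a scramble siRNA (siCtrl) and 3 with siRNA against HBO1 (siHBO1), all collected 48 h after transfection. HBO1 is the protein of KAT7, a lysine acetyltransferase of the MYST family that acetylates histones in complexes with scaffold proteins of the BRPF and JADE families. The series asks what role HBO1 has in this cell line, and the comparison made is siHBO1 against siCtrl. Between 42.2% and 44.3% of the 47314 probes were detected per array. Log2 values of all tested genes correlated at 0.977 to 0.994 between arrays of the same group (mean 0.983) and at 0.973 to 0.989 between arrays of different groups (mean 0.985), across genes, which are not independent replicates.

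KAT7, the gene targeted, had lower values on all 3 siHBO1 arrays than on any siCtrl array. Its log2 value was 5.93, 6.49 and 6.45 on siCtrl 1 to 3 (mean 6.29 ± 0.31, SD, n = 3) and 4.77, 5.22 and 5.45 on siHBO1 1 to 3. The log2 change was -1.14 (SE 0.25, 95% interval -1.70 to -0.58), or 2.21-fold lower after background correction, a fold that depends on that correction since the probe was above background on 1 of 3 siHBO1 arrays. The 8 measured partners of HBO1 had log2 changes of 0.16 for BRPF1, 0.03 for BRPF3, -0.03 for ING4, -0.02 for ING5, 0.04 for JADE1, 0.36 for JADE2 (SE 0.31), -0.25 for JADE3 (SE 0.17) and -0.00 for MEAF6, and 0 of the 8 passed the test. Other probes of ING5, JADE1 and MEAF6 differed in sign from those given, with log2 changes of 0.16, -0.03 and 0.04, and a further probe of JADE1 gave 0.13. The exact permutation test of KAT7 gave p = 0.1, the smallest that 3 arrays against 3 allow, and in limma its adjusted p was 0.999, rank 18 of 16692 rows by p. KAT7 has 1 measured probe, which was dim: it was detected at p under 0.05 on 3 of 3 siCtrl arrays and on 1 of 3 siHBO1 arrays (detection p 0.274, 0.0584 and 0.0247), and the fold came to 1.29 without background correction, 1.61 with an offset of 50 and 1.63 in the authors' processed values.

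**Figure D1:**
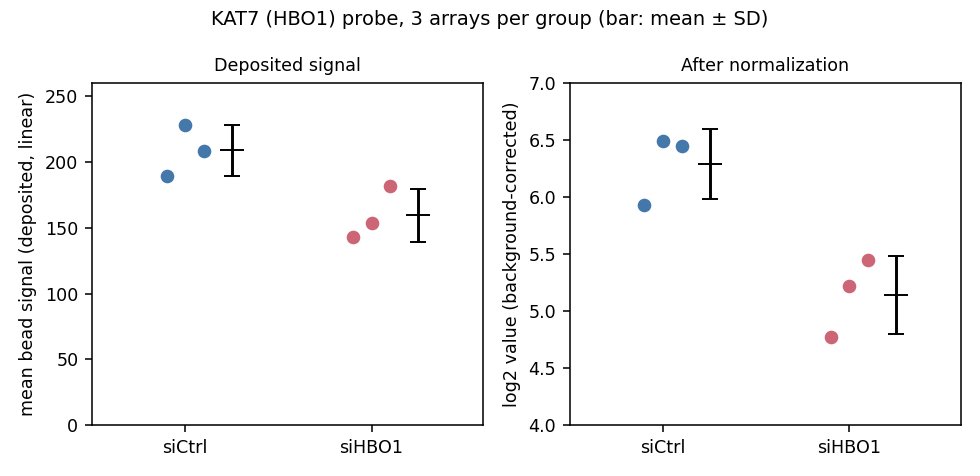
KAT7 probe on each of the 6 arrays, as deposited mean bead signal on a linear axis (left) and as normalized log2 value (right); points are arrays and bars are the mean with the SD of 3 arrays. The siHBO1 signals of 143, 153 and 182 lie below the siCtrl signals of 190, 228 and 209.

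The genes with the smallest p among those lower in siHBO1 were headed by RNF141, a RING finger protein, with a log2 change of -1.46 (SE 0.17, limma adjusted p 0.143), and CHORDC1, an HSP90 co-chaperone, with -1.38 (SE 0.19, adjusted p 0.214). RABL2B, a small GTPase linked to cilia, differed by -1.27 (SE 0.19, adjusted p 0.30), CDR2 by -0.83 (SE 0.13, adjusted p 0.30) and LIFR, the receptor of leukaemia inhibitory factor, by -1.40 (SE 0.23, adjusted p 0.446). Next by p were SLIRP, a mitochondrial RNA-binding protein (-0.37, SE 0.07), the vesicular transporter SLC18B1 (-0.89, SE 0.16), the translocon-associated protein SSR2 (-0.63, SE 0.12), the phospholipase NAPEPLD (-0.86, SE 0.17) and DERL1, which acts in degradation of proteins from the endoplasmic reticulum (-0.60, SE 0.12). Their adjusted p ranged from 0.687 to 0.911, so none of the 10 passed the test. RNF141, CHORDC1 and RABL2B did pass with array weights, with the replicate number as a block and with the leading residual component as a covariate. The closing section describes the calibration of that covariate. RABL2A and RABL2B are near-identical copies whose probes may pick up each other's transcripts, and RABL2A, chosen after its values were seen, had a log2 change of -1.43. Another probe of RABL2B gave -0.88, another of NAPEPLD -0.65 and another of SSR2 -0.18. The unnamed probe ILMN_3274914, also chosen after its values were seen, had the smallest p of all with a log2 change of -2.11 (SE 0.25, adjusted p 0.143). Without background correction the changes were -0.96 for RNF141, -0.58 for LIFR, -0.44 for NAPEPLD and -1.24 for ILMN_3274914.

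Among genes higher in siHBO1, SLFN5, a Schlafen family member, had the smallest p, with a log2 change of 1.04 (SE 0.21, limma adjusted p 0.911). It was followed by GPSM3, a modulator of G protein signalling (0.73, SE 0.17), the golgin gene GOLGA8A (0.87, SE 0.21), the ribosomal protein gene RPS24 (0.30, SE 0.08), the brain form of glycogen phosphorylase PYGB (0.42, SE 0.11) and the calcium-binding S100A16 (0.58, SE 0.15). The remaining 4 of the 10 were CHRNA9, a nicotinic acetylcholine receptor subunit (1.00, SE 0.26), the tetraspanin TSPAN2 (1.01, SE 0.27), the acyltransferase LPCAT4 (0.65, SE 0.18) and ZNF503 (0.66, SE 0.18). All after SLFN5 had an adjusted p of 0.999. CHRNA9 was detected on 1 of 3 siCtrl arrays and TSPAN2 on 2 of 3, another probe of RPS24 gave a log2 change of -0.14 against 0.30, another of TSPAN2 gave 0.55, and GOLGA8A belongs to a family of near-identical copies, so its value is uncertain. Without background correction the changes were 0.42 for SLFN5, 0.32 for GPSM3, 0.41 for GOLGA8A, 0.32 for CHRNA9, 0.35 for TSPAN2 and 0.28 for LPCAT4.

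Across all 16692 rows, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.143. At an unadjusted p under 0.05 there were 638 rows, 300 higher and 338 lower, where 834.6 would be reached by chance. In 915 rows all siHBO1 arrays lay above all siCtrl arrays and in 765 below, 10.1% of rows against 10% by chance. At least 2-fold differences were seen in 4 rows higher and 12 lower. These counts depend on the background correction. Without it SLFN5 (0.42), TSPAN2 (0.35), RNF141 (-0.96) and LIFR (-0.58) were under 2-fold. CHORDC1 (-1.17), RABL2B (-1.11) and ILMN_3274914 (-1.24) were still over 2-fold lower. The 95% interval of a gene's change had a median width of 0.45 on either side, or 1.36-fold. The count of 638 was 298 without siCtrl 3, 404 without siHBO1 1 and 1502 without siHBO1 2. It was also above the chance count with array weights (1261), the leading residual component as a covariate (1184) and without the 2 arrays at its ends (1732), and the calls of 4 lower rows that some other fits made are given with those fits in the closing section.

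**Figure D2:**
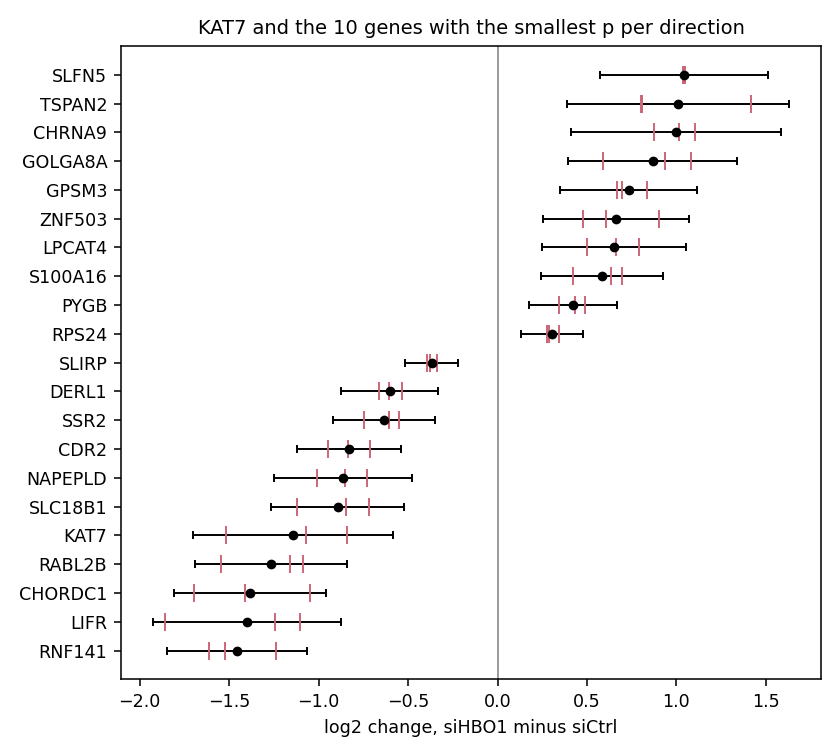
Log2 change, siHBO1 minus siCtrl, of KAT7 and of the 10 genes per direction with the smallest p. Black points are the changes with their 95% interval, and red ticks are the 3 siHBO1 arrays, each against the siCtrl mean. RNF141 is lowest at -1.46 and SLFN5 highest at 1.04, and none passed the adjusted test in the fit shown. RNF141, CHORDC1 and RABL2B passed with array weights, the replicate block and the leading residual component as a covariate.

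Lists of chromosome replication and cell division genes had medians within 0.16 log2 of 0. Of 26 replication licensing genes, 16 had negative and 10 positive values (median -0.04), with GINS4 at 0.63 (SE 0.23) and MCM6 at -0.25 (SE 0.10). Of 31 DNA synthesis genes, 18 were negative (median -0.05), with RPA3 at -0.39 and TK1 at 0.41. Of 33 mitosis genes, 23 were negative (median -0.08), with CDK1 at -0.30 (SE 0.11, another probe -0.53) and CENPE at -0.33, and camera gave this list an adjusted p of 0.391. Of 12 cell cycle inhibitors, 8 were negative (median -0.09), with CDKN1B at -0.43 (another probe 0.09) and RB1 at -0.29. Of 15 replication-dependent histone genes, 10 were positive (median 0.16), with H2BC5 at 0.30 (another probe 0.05) and H2AC18 at 0.34 (another probe -0.05). The 19 p53 targets had a median of 0.09, with TP53I11 at 0.48 and POLH at -0.37, and the 17 DNA repair genes one of -0.02, with TIPIN at -0.27 and TP53BP1 at 0.24. The 8 HBO1 partners had a median of 0.02, and the 12 other acetyltransferases one of 0.05, with KAT2B at -0.33 and HAT1 at -0.47. None of these genes passed the test over all genes.

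Of 24 mesenchymal genes, 16 were positive (median 0.10), with the integrin ITGA5 at 0.41 (SE 0.13) and the collagen cross-linking enzyme LOX at 0.68 (SE 0.27). Camera gave this list the smallest adjusted p of all, 0.281, and an adjusted p of 0.995 with an estimated correlation. That estimate was 0.017, close to the preset 0.01, and the unadjusted camera p was 0.072 with it against 0.010 with the preset. The 14 epithelial genes had a median of 0.13, with CLDN3 at -0.30 and JUP at 0.65. Among 10 stem cell genes (median 0.16), BMI1, a Polycomb protein, was at -0.53 (SE 0.12), with an adjusted p of 0.0142 adjusted over the list alone and 0.999 over all genes, the only list member past either, and NES was at -0.39. HOX genes had a median of 0.04 over 20 members, with HOXC8 at 0.43 and HOXD4 at -0.36, and the 17 Wnt genes one of -0.05, with WNT5A at -0.23 and ZNRF3 at 0.22. The 18 TGF-beta and YAP targets had a median of -0.03, with TGFBR1 at -0.44 and ID1 at 0.19 (another probe 0.00). The 11 steroid hormone genes had a median of 0.09, with KLF9 at 0.28 and XBP1 at 0.23, and the 18 ERBB and growth factor genes one of 0.05, with NRG1 at -0.56 and IGFBP3 at -0.23.

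Among stress, immune and metabolic genes, 0 passed the test over all genes. The 16 NF-kB and cytokine genes had a median of 0.17, 12 of them positive, with TNF at 0.61 and TNFAIP2 at 0.30. Their mean deviated from the group mean by 0.94 on siCtrl 1 and -0.84 on siHBO1 3, so single arrays can move this value. The 27 interferon response genes had a median of 0.06, with PSMB9 at 0.66 (another probe 0.10) and IFIH1 at -0.37, and the 12 RNA interference genes one of 0.10, with TNRC6C at 0.42 and DICER1 at -0.31 (another probe -0.68). The 23 stress and unfolded protein response genes had a median of 0.10, 19 of them positive, with SLC7A11 at -0.26 and VLDLR at 0.44. The 22 apoptosis regulators had a median of 0.05, with TNFRSF10A at 0.51 and APAF1 at -0.35 (another probe 0.13). Medians were 0.01 over 23 cholesterol and fatty acid genes (DHCR7 0.35 and by another probe 0.22, ELOVL6 0.28 and by another probe 0.56), 0.05 over 26 hypoxia and glycolysis genes (HIF1A -0.29, CA12 -0.51), 0.02 over 23 ribosome biogenesis genes (SRM 0.38, NME1 -0.13 and by other probes -0.45 and -0.24) and 0.01 over 23 oxidative phosphorylation genes (CYC1 0.25, COX7B -0.46). The 17 reference genes had a median of 0.02, with B2M at -0.17 (another probe 0.04) and GUSB at 0.18. Markers of other cell types were few: 8 leukocyte markers had a median of -0.00, with CD14 at 0.38 and CD52 at 0.32, and of the fibroblast and endothelial markers COL1A1 (0.35, SE 0.66) and COL1A2 (0.20, SE 0.64, another probe 0.51) were measured, too few to test.

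Of the 28 lists tested with camera, 0 passed an adjusted p under 0.05 with the preset correlation and 0 with an estimated one, and 2, the mesenchymal and the mitosis lists, had an unadjusted p under 0.05. The median, mean and test of the stem cell, ERBB and leukocyte lists differed in sign. Under median scaling, which shifted the median of all genes to -0.05, 7 list medians changed sign, those of the HBO1 partners, other acetyltransferases, ERBB, apoptosis, cholesterol, ribosome biogenesis and leukocyte lists, and so did BRPF3 and JADE1 among the named genes. Of the 56 members of these lists named for their p, 2 per list, 20 had log2 changes smaller by over 1.5 times without background correction. Among them were TNF at 0.19, PSMB9 at 0.29, JUP at 0.27, TGFBR1 at -0.13 and TNRC6C at 0.13. The others were TP53I11, POLH, IFIH1, TNFAIP2, CLDN3, NES, WNT5A, HOXC8, HOXD4, KLF9, TNFRSF10A, VLDLR, DHCR7, CD14 and CD52. Among the HBO1 partners outside that count, ING4 and ING5, both near 0, were also smaller by over 1.5 times. TNF, TNRC6C, TP53I11 and CD52 were detected on 1 of 3 siCtrl arrays. With the preset correlation, 6 lists passed without siCtrl 1, 4 without siHBO1 3 and 1 without siHBO1 1, and with an estimated correlation 0 lists passed in any of these fits.

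**Figure D3:**
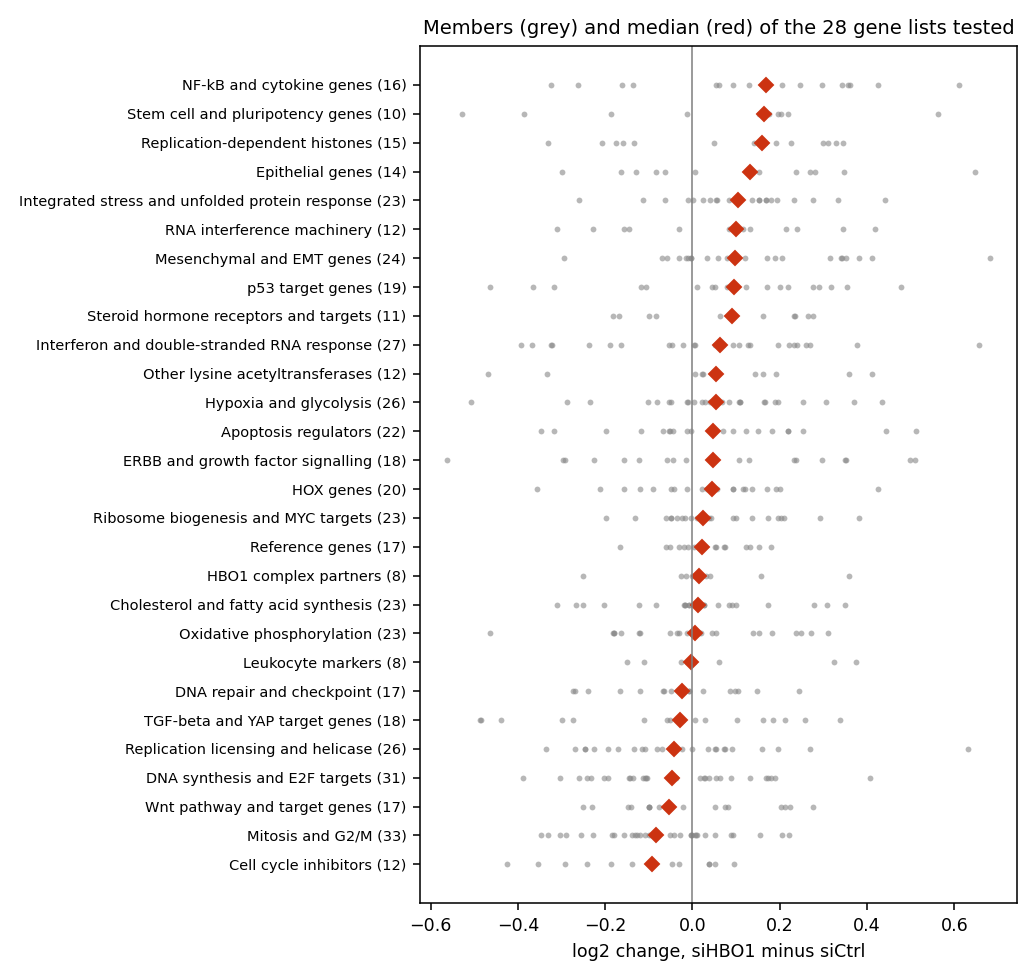
Log2 change, siHBO1 minus siCtrl, of each measured member (grey) of the 28 gene lists tested, with the list's median (red) and the number measured in brackets. The medians run from -0.09 for cell cycle inhibitors to 0.17 for NF-kB and cytokine genes.

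Arrays of one group differed from each other in the same gene groups. The mean of the NF-kB and cytokine genes deviated from its group's mean by 0.94, -0.52 and -0.42 log2 on siCtrl 1 to 3 and by 0.70, 0.14 and -0.84 on siHBO1 1 to 3. The stress and unfolded protein response genes deviated by 0.49, -0.15 and -0.34 on the siCtrl and 0.43, 0.08 and -0.51 on the siHBO1 arrays. The HBO1 partners spanned 0.08 log2 over the 6 arrays and the NF-kB genes 1.78.

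**Figure D4:**
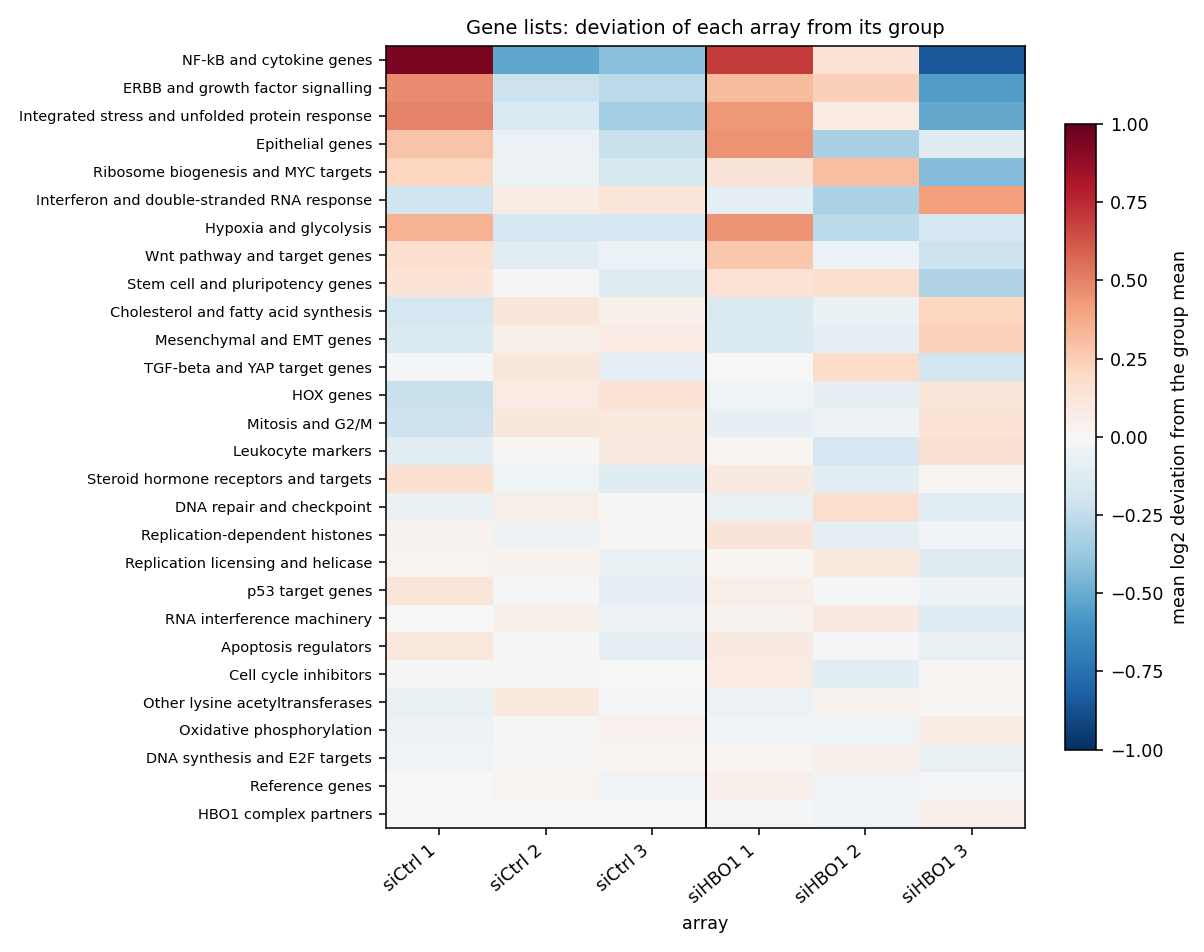
Mean log2 deviation of each gene list (rows) on each array (columns) from the mean of that array's group, red above and blue below. NF-kB and cytokine genes reach 0.94 on siCtrl 1 and -0.84 on siHBO1 3, and the HBO1 partners span 0.08.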

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

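The covariate and the fit without 2 arrays, described here, were chosen after the data were seen. KAT7 had a negative change in all 19 alternatives that gave it a value (-1.44 to -0.36), with adjusted p from 0.135 to 1.00 and 0 past the threshold; detection on all 6 arrays removed its probe. The 20 genes named for their p, 10 per direction, had the reported sign in 396 of 396 values, 9 of them past the threshold. These genes were picked by p on the same arrays, and each had all siHBO1 arrays on one side of all siCtrl arrays. Fits that leave out, weight or block arrays, or add the covariate, could therefore not change their sign. The same holds for KAT7, whose siHBO1 values all lay below its siCtrl values, so its constant sign in those fits was fixed in advance. In 16 of 20 alternatives 0 genes were called, and in 13 of 21 alternatives 0 lists. Array weights, the replicate block and the leading residual component as a covariate each called 4 lower rows, in each case RNF141, CHORDC1, RABL2B and ILMN_3274914. The replicate numbers were not taken to pair the samples, since the labels name nothing shared. Deviations of same-numbered arrays correlated at 0.57, 0.02 and 0.48, and those of unlike-numbered arrays of different groups at -0.57 to 0.31. By these values 4 of 6 arrays deviated most like their own number, a hint of pairing from the data and not the design. The block gave 1187 rows at an unadjusted p under 0.05, with 28 lower and 7 higher under 0.001. Its smallest limma adjusted p was 0.0038, against 0.143 without the block. The covariate is not calibrated in general: on simulated arrays with no change it called rows in 103 of 200 draws of random scores (median 1, mean 530, most 3836), and in 20 draws with the scores of the real arrays it called 0. Lists passed in 1 case with median scaling (mesenchymal), 1 with every probe (mitosis), 4 with array weights, 1 with the covariate and from 0 to 6 with an array left out. With an estimated correlation 0 passed in any alternative. In the reported fit the estimate was 0.41 for mitosis, 0.64 for NF-kB, 0.65 for stress, 0.42 for hypoxia and 0.74 for ribosome biogenesis genes. These lie far above the preset 0.01, which is therefore lenient for these lists, while the mesenchymal list had 0.017. Estimates over 0.3 were found for 6 lists. Why calls with the preset changed between fits was not tested. Without siCtrl 1 and siHBO1 3, the arrays at the ends of the component, 1 gene (CXCL8) was higher and 8 lists passed, but the arrays left have scores of 12.5 and 18.9 (siCtrl) against -23.2 and -11.6 (siHBO1), so by construction this fit compares the sides of that component. Slide as a block was not run, since the labels give no slides. Dim probes limit fold changes, as for KAT7.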

Other observations

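SKOV-3 control cells had these programmes detected. At a detection p under 0.01 on all 3 siCtrl arrays, 33 of 33 mitosis genes, 23 of 23 oxidative phosphorylation genes, 8 of 8 HBO1 partners and 17 of 17 reference genes were detected. Among epithelial genes 12 of 24 were, with CDH1, CLDN4, CLDN7, ESRP1 and GRHL2 not detected on all 3 siCtrl arrays. The cell cycle inhibitors CDKN2A and CDKN2B were not detected on all 3, and 12 of 14 in that list were. Of the stem cell genes 8 of 18 were detected, without SOX2, NANOG and POU5F1. Of the steroid hormone receptors and targets 11 of 18 were, among them ESR1 and NR3C1 but not ESR2 and PGR. Of the leukocyte markers 3 of 21 were detected, and of the fibroblast and endothelial markers 2 of 19.

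The tests of probes near background, of the groups and of the replicate number were chosen after the result was seen. The leading component of the 6 arrays did not follow the groups. IL6 had log2 values of 11.17, 7.69 and 7.16 on siCtrl 1 to 3 and 10.68, 9.50 and 6.87 on siHBO1 1 to 3, a range of 19.8-fold. IL1A, CXCL2, ATF3 and HBEGF were also highest on siCtrl 1, with ranges of 13.2-fold, 11.3-fold, 8.72-fold and 5.41-fold. PDZK1 (9.53-fold), COL1A1 (8.25-fold) and IFIT1 (5.22-fold) ran the opposite way, highest on siHBO1 3. These genes were chosen after their values were seen.

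The first component of all values, found without using the groups, held 43.9% of the variance. The siRNA groups explained 0.0169% of the arrays' scores on it. The pattern was picked out for not following the groups, so this low share describes it and is no separate test. The component used below is that of the residuals, which held 51.9% of the variance left within groups. By construction it cannot follow the groups. Signal level of the probes explained 0.0237% of the genes' loadings. Quantile normalization removes smooth shifts with signal level, so this low share alone cannot exclude them. With median scaling in its place, which leaves such shifts in, the loadings correlated at 0.997 with those used. Neither quantile normalization nor a smooth shift with signal level therefore accounts for the component. A larger scatter of dim probes was not tested. A shared replicate number remains a possible source, since the labelled pairing had the highest sum of score products in 1 of 6 pairings, too few to decide, and differences in culture or stress were not tested. For the counts of higher genes, lower genes and lists, the real values are 0, so 10 of the 10 splits of the 6 arrays give as many whatever the data, and this decides nothing. The 10 splits are also too few for a share under 0.05. The highest other values were 301 genes on one side and 11 lists, from the split of siCtrl 1, siHBO1 1 and siHBO1 2 against the rest, which called 548 genes. That split parts the arrays by the sign of their scores, so it restates this structure of the samples and is no separate support for it.

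More rows were lower than higher at small p: 15 lower and 1 higher at an unadjusted p under 0.001, in all 16, where 16.7 would be reached by chance. Probes near background do not account for it, since 2 of the 15 were not detected at p under 0.01 on all 6 arrays. Leaving out an array gave 9 lower rows without siCtrl 1, 6 without siCtrl 2, 8 without siCtrl 3, 8 without siHBO1 1, 70 without siHBO1 2 and 10 without siHBO1 3, with 0 to 3 higher. Counts of lower and higher rows were 28 and 2 with the covariate, 28 and 7 with the replicate block and 25 and 3 with array weights. Without the 2 end arrays they were 54 and 61, so the excess of decreases did not hold there. That fit by construction compares the sides of the component, so it cannot decide whether the excess holds between the siRNA groups. In 2 of the 10 splits a side had at least 15 rows, the real split and that of siCtrl 1, siHBO1 1 and siHBO1 2 against the rest. The latter had 248 rows on one side and 183 on the other, so its count does not measure an excess in one direction. It also parts the arrays by the sign of their scores. The next highest count on a side was 9, with 9 on the other. With the component as a covariate 3 of the 10 splits gave at least the real 4 (highest other 576). These splits are too few for a share under 0.05, and an effect of the siRNA, on HBO1 or off target, was not tested.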
